A study of Mus musculus with 64 samples.

How the data were processed

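The series holds stranded RNA sequencing libraries from striatum and cerebral cortex of C57BL/6 mice aged 6 months, 64 libraries from 32 mice. Per the labels there were 4 genotypes, Wild type, Tcerg1+/-, Het (Q140) KI and Het (Q140) KI X Tcerg1+/-, each with 4 females and 4 males, and the last 2 are called Q140 and Q140 Tcerg1+/- here. The molecule label is total RNA, while the titles say mRNA. RNA was extracted with an RNeasy kit and libraries were made by the TruSeq stranded protocol. The protocol text names only striatal tissue, while the tissue label and the marker genes give cortex for 32 libraries. Both libraries of a mouse were joined through the description label. The labels also give the plate well of each library, with cortex in columns 1 to 4 and striatum in columns 5 to 8, so tissue and plate column cannot be separated.

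The authors deposited a table of raw read counts and a table of FPKM (fragments per kilobase of gene, scaled to the library total), both for 48795 genes and all 64 libraries. The deposited notes name STAR 2.7.5c, SAMtools 1.10 and HTSeq 0.12.3 and the genome build GRCm38 (mm10), without their order, and state neither the annotation release nor the strand setting. The count values were whole numbers without scaling. Deposited FPKM equalled the count divided by 1 gene length and by the library's total count in 8459 of 8459 genes with a mean count over 500 (tolerance 0.01 bases), so it carries no further normalization. Of the gene identifiers, 48435 were found in GENCODE M21, which gave coordinates, and the chromosome agreed for all 48435 and the strand for 48421. Symbols used more than once (134) were kept apart by identifier.

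Labels were checked on the data. The X-inactivation transcript Xist averaged 832 CPM in female cortex and 1618 in female striatum and 0.142 and 0.221 in males, and the Y-linked genes followed the labels. Striatal and cortical marker genes separated the tissues, and none of the 2016 pairs of libraries had identical counts. The labels do not say that replicate numbers pair mice across genotypes, and mice were not treated as paired. The median correlation between libraries with the same number was 0.0353 in striatum and -0.0331 in cortex after removal of genotype and sex effects, and the same number was the best match among mice of the same sex for 11 and 10 of 32 libraries, where chance gives 8, so a weak link is not excluded.

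Total counts were 22826838 to 31519518 per striatal library and 26030913 to 33553390 per cortical library. Levels are given as CPM, counts scaled to a common library size with TMM factors, means with SD over mice. Precision of group means was taken from the 8 mice per group. Ranges of raw counts are given for genes near 0 and cover counting error only.

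Genes were tested with edgeR 4.0.16 in R 4.3.3 (data.table, version 1.17.8, for input). Each tissue was fitted on its own, with genes kept by filterByExpr on genotype, TMM factors, robust estimateDisp and glmQLFit, and genotype plus sex as terms, so that the genotypes shared 1 estimate of spread from 32 libraries. Contrasts were Q140 against wild type, Tcerg1+/- against wild type, Q140 Tcerg1+/- against Q140, Q140 Tcerg1+/- against Tcerg1+/-, their interaction, the average Q140 effect and the difference of the Q140 effect between sexes (in a fit of genotype by sex). Differences between tissues were tested on all 64 libraries with mouse as a block, over 18742 genes. Quasi-likelihood F tests were two-sided, a gene was called at a Benjamini-Hochberg adjusted p below 0.05, and no fold threshold was used. Fold changes are log2, with a prior count of 2 in displayed levels.

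In every contrast Tcerg1 and Htt were named. Then, among called genes with a mean of at least 1 log2 CPM, the 10 largest log2 fold changes in each direction were taken, or 5 in each direction for interactions and for differences between tissues or sexes. From each list came up to 4 called members with the smallest p, or 2 members if none was called. The text names subsets of these in that order. Genes named although they lie below the level minimum include Gm2420, Wt1, Onecut1 and, in striatum, Satb2 and Neurod2. Gm2420 came in as a called neighbour of Htt and the others through their lists.

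Gene lists with 24 titles were tested in 5 contrasts per tissue, 240 tests adjusted together. They cover cell types (projection neuron, direct and indirect pathway, interneuron, cortical excitatory neuron, astrocyte, oligodendrocyte lineage, microglia, endothelial cell and pericyte, choroid plexus and ependyma, red blood cell, thalamic and septal neuron) and processes (immediate early, clustered protocadherin, Polycomb-silenced developmental regulators, mitochondrially encoded and nuclear-encoded respiratory chain, cytosolic ribosomal protein, cholesterol biosynthesis, heat shock, mismatch repair and other onset loci, splicing and elongation, glutamate receptor and postsynaptic density, interferon response). Camera (limma 3.58.1) was run with a preset correlation of 0.01 and again with an estimated correlation, and fry gave a self-contained test of direction. For the projection neuron list in Q140 striatum fry gave an adjusted p of 7.90e-17. Neighbours of Tcerg1 and Htt were the genes that start within 10 Mb, compared with all other tested genes by two-sided Fisher's exact tests. These tests, lists, contrasts, named-gene rule and alternatives were chosen before the data were examined, apart from the average effect of the Tcerg1+/- label with its alternatives, the fit without a pair of mice, and the alternatives for the cortical excitatory genes (each compared striatal library left out) and for the glial and vascular markers (other scalings).

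The Q140 score of a mouse was the mean log2 CPM of the genes called for the average Q140 effect, signed by direction. Its interaction was tested by 100000 permutations of the Tcerg1 label within Q140 status (two-sided), with a percentile interval of 95% from 10000 bootstrap draws of mice within genotype. Across-gene correlations are descriptive.

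Alternatives, 1 at a time, were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, limma-trend on log2 FPKM with a pseudocount of 0.1 or 1, a mean count of at least 50 in place of the filter, no filter, no sex term, plate column as an added term, replicate number as a block in place of sex, only the libraries compared, no mouse block for tissue differences, an estimated inter-gene correlation, the Q140 score from Q140 against wild type alone or from the projection neuron list, and each library left out. Counts of called genes were set against 100 random splits of the mice (24 for tissue differences).

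The tests were tested on simulated data, negative binomial counts drawn with the mean levels and dispersions of the libraries, in which 50 genes per fold were changed. For Q140 against wild type in striatum 74% of genes changed 1.5-fold and 86% of genes changed 2-fold were recovered, for the Tcerg1+/- label 86% and 88%, and for the tissue difference 70% and 88%. Of 100 random unchanged lists camera called 1 in striatum and 4 in cortex at an unadjusted p below 0.05. The simulated genes were drawn independently of each other, so this does not test the preset correlation on real data. No library was excluded, and sequence reads, splicing and allele-specific signal were not analysed here because the deposited tables hold gene totals only.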

Results

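Gene expression was measured by stranded RNA sequencing of the striatum and the cerebral cortex of 32 mice aged 6 months. The mice were labelled wild type, Tcerg1+/-, Q140 or Q140 Tcerg1+/-, with 8 mice per genotype, 4 female and 4 male, and each mouse gave a library from each tissue, which made 64 libraries. Q140 is short for the label Het (Q140) KI, a heterozygous knock-in of an expanded CAG repeat in the mouse Htt gene that models Huntington disease. Tcerg1 encodes a nuclear protein that couples transcription elongation to splicing and binds huntingtin. The cross asked whether a lower dose of Tcerg1 changes what the Q140 allele does to expression. Counts summed to between 22826838 and 31519518 per library in striatum and between 26030913 and 33553390 in cortex. After the filter on low counts, 17901 genes were tested in striatum and 17752 in cortex.

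The targeted genes came first. Tcerg1 (ENSMUSG00000024498, GRCm38 chromosome 18, 42511487 to 42575793) was higher, not lower, in every group labelled Tcerg1+/-. In striatum its mean level was 79.6 CPM (counts scaled to a common library size) ± 3.22 (SD, n = 8) in wild type and 111.2 ± 2.52 (n = 8) in Tcerg1+/-, and 96.8 ± 3.02 (n = 8) in Q140 and 137.5 ± 4.42 (n = 8) in Q140 Tcerg1+/-. In cortex the same groups held 83.3 ± 3.31, 124.7 ± 4.20, 85.0 ± 3.48 and 126.7 ± 4.09 CPM (n = 8 each). All 8 labelled libraries lay above all 8 of their comparison group in each of these 4 comparisons, with log2 fold changes of 0.48 (SE 0.0257, edgeR adjusted p = 9.79e-17) and 0.51 (SE 0.0253, adjusted p = 9.58e-18) in striatum and 0.58 (SE 0.0271, adjusted p = 7.37e-19) and 0.58 (SE 0.0271, adjusted p = 1.10e-18) in cortex. The labels do not say what kind of allele the mice carried or which part of the transcript it leaves, so reads over the gene do not give the amount of functional Tcerg1. The groups are therefore called by their label, and every direction given for the Tcerg1+/- label below is that of mice in which Tcerg1 reads were higher.

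The Q140 label also raised Tcerg1 reads, in striatum alone. The log2 fold change was 0.28 (SE 0.0257, edgeR adjusted p = 1.49e-11) in Q140 against wild type and 0.31 (SE 0.0252, adjusted p = 9.00e-13) in Q140 Tcerg1+/- against Tcerg1+/-, and neither comparison passed in cortex, at 0.03 (adjusted p = 0.805) and 0.02 (adjusted p = 0.918). Striatum minus cortex, the Q140 effect on Tcerg1 differed by 0.25 (SE 0.0375, adjusted p = 2.42e-06). Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534) went from 229.9 CPM ± 9.42 (SD, n = 8) in wild-type striatum to 209.9 ± 8.79 (n = 8) in Q140 striatum, a log2 fold change of -0.13 (SE 0.0289, adjusted p = 4.02e-04) that did not pass on the deposited FPKM (adjusted p = 0.0789). It fell in Q140 Tcerg1+/- against Tcerg1+/- striatum, by 0.15 on the log2 scale (adjusted p = 4.29e-05), while the cortical values of -0.06 (adjusted p = 0.569) and -0.07 (adjusted p = 0.577) did not pass. Htt did not pass for the Tcerg1+/- label in either tissue, with adjusted p values of 0.927 and 0.979 in striatum and 0.973 and 0.998 in cortex.

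**Figure D1:**
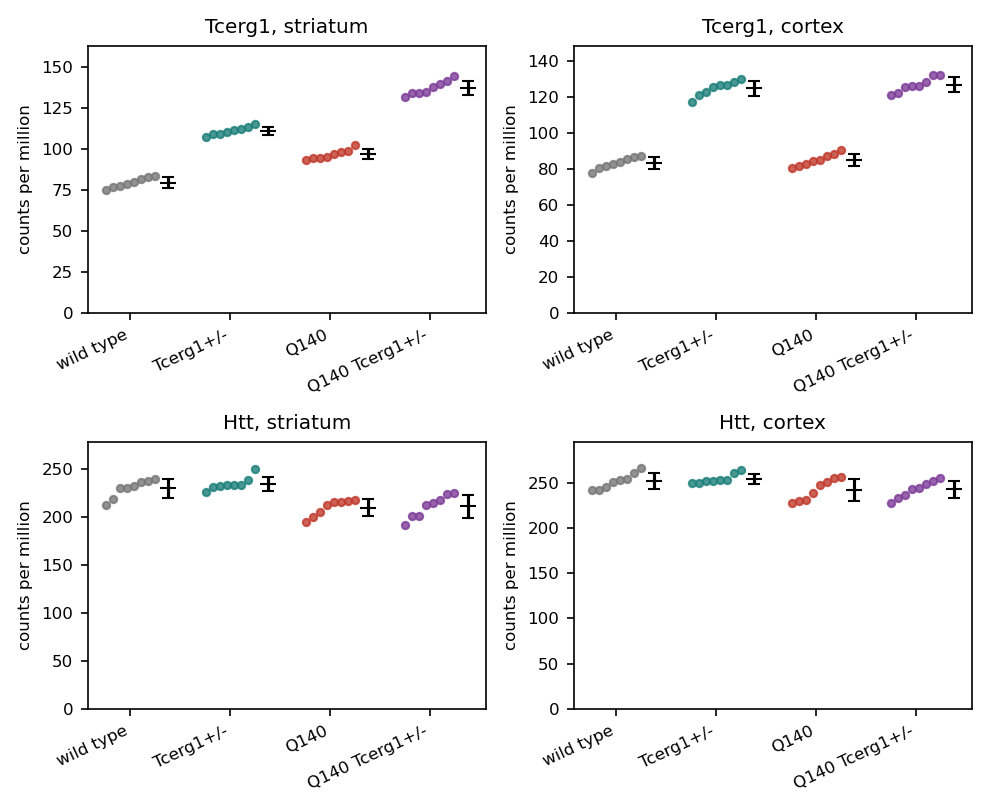
CPM (y axis, from 0) of Tcerg1 and Htt in each library of striatum and cortex by genotype (x axis, n = 8 per group); points are libraries ordered by level within the group, and the bar at the right of each group is the mean with 1 SD. Tcerg1 in wild-type striatum lies between 75.0 and 83.9 CPM and in Tcerg1+/- striatum between 107.7 and 115.2.

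What the Q140 allele changed in striatum was asked by comparing Q140 with wild type. The genes that mark striatal projection neurons fell. All 30 genes of the projection neuron list passed downward, both over all genes and adjusted over the list alone, with a median log2 fold change of -0.48. Among them were the cyclic nucleotide phosphodiesterase Pde10a (log2 fold change -0.85), the phosphoprotein Arpp21 (-0.79), the adenylyl cyclase Adcy5 (-0.73) and the G protein regulator Rgs9 (-0.72, SE 0.0259). The indirect pathway list, which marks the neurons that carry the D2 dopamine receptor, had 0 genes that rose and 5 that fell of 7 (also 5 adjusted over the list alone), with a median of -0.60 and with Penk, which encodes enkephalin, at -1.15, Adora2a at -0.78 and Drd2 and Gpr6 at -0.60. The direct pathway list was mixed, with 3 that rose and 4 that fell of 9 (the same adjusted over the list alone). Its dopamine receptor Drd1 (-0.61) and muscarinic receptor Chrm4 (-0.67) fell and the transcription factor Isl1 rose (0.30), and its median of -0.06 changed sign on FPKM.

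Beyond the lists, the largest rises among genes of at least 1 log2 CPM included Sfmbt2 (ENSMUSG00000061186, chromosome 2, 10370510 to 10595253), a Polycomb group gene, and Dsp (ENSMUSG00000054889, chromosome 13, 38151294 to 38198577), which encodes the desmosome protein desmoplakin. Sfmbt2 went from 2.36 CPM ± 0.473 (SD, n = 8) to 8.66 ± 1.45 (n = 8), a log2 fold change of 1.89 (SE 0.105, edgeR adjusted p = 1.64e-17), and Dsp rose by 1.87 (SE 0.212, adjusted p = 7.21e-09). Next in size were Tmc3 (1.53), Fam196b (a 2.39-fold rise), Rprm (1.21), Ipcef1 (1.19), Pcdh20 (1.18) and the desmoglein gene Dsg2 (1.11). Among these rises stood Gm6089 (3.21, SE 0.451) and Gm5067 (1.69), which are processed pseudogenes on chromosome 5 whose reads cannot be assigned with certainty. The largest fall was that of the glutathione peroxidase Gpx6 (ENSMUSG00000004341, chromosome 13, 21312125 to 21319624), from 12.8 CPM ± 2.39 (n = 8) to 2.84 ± 0.663 (n = 8), a log2 fold change of -2.17 (SE 0.136, adjusted p = 3.60e-14). The copine gene Cpne9 (ENSMUSG00000030270, chromosome 6, 113282307 to 113305627) followed at -2.09 (SE 0.133, adjusted p = 1.16e-13). Ddit4l, an inhibitor of mTOR signalling, went from 41.2 CPM ± 2.69 (n = 8) to 10.8 ± 2.25 (n = 8), and Vwa7 (-1.87), Sec14l3 (-1.85), the angiotensin receptor gene Mas1 (-1.71), Gm9754 (-1.70), Slc4a11 (-1.69), Serpinb1b (-1.68) and Atp6v1c2 (-1.64) also fell.

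In all, 5746 of 17901 genes passed at an edgeR adjusted p below 0.05, 2968 upward and 2778 downward, and 7253 had an unadjusted p below 0.05. Changes of more than 1.5-fold were seen in 635 of them, 223 upward and 412 downward. On FPKM, which is scaled to the library total, the median of all genes moved from 0.00832 to 0.0715 on the log2 scale, and limma-trend called 7671 genes, 5848 upward and 1823 downward, so the balance of small rises and falls depends on the scaling.

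The clustered protocadherins, adhesion proteins that give neurons a surface identity, rose as a group in Q140 striatum. Of 57 tested, 34 rose and 5 fell (35 and 6 adjusted over the list alone), with a median of 0.28, and examples were Pcdhb2 (0.94), Pcdhb12 (0.74), Pcdhb9 (0.65) and Pcdhb22 (0.58). Glutamate receptor and postsynaptic genes went the other way, with 3 that rose and 15 that fell of 23 (the same adjusted over the list alone), among them the scaffold Shank3 (log2 fold change -0.58), Grm1 (-0.41) and the kinase Camk2b (-0.35). Of the cortical excitatory neuron list, 5 of 11 rose and 0 fell (the same adjusted over the list alone), with Satb2 (1.81), Neurod2 (1.52), Rprm (1.21) and Lamp5 (0.15). Satb2 stayed far below its cortical level, at 0.229 CPM in wild-type striatum, 0.849 in Q140 striatum and 115.6 in wild-type cortex. Neurod2 was as low, at 0.199 CPM in wild-type striatum and 0.577 in Q140 striatum. The striatum of Q140 M4 stood apart, with the highest Satb2 of its group (2.03 CPM, others 0.423 to 1.29) and the highest Slc17a7 (12.5 CPM, next 6.11), and without it 5 of the 11 rose and 0 fell, with Satb2 at 1.53 (adjusted p = 0.00132) and Neurod2 at 1.41 (adjusted p = 0.00254). The heat shock list had 7 that rose and 0 that fell of 16 (the same adjusted over the list alone), with Hspa1a (0.71) and Hspa8 (0.31). In the list of developmental regulators silenced by Polycomb, 2 of 6 rose and 0 fell (the same adjusted over the list alone). They were Wt1, from 0.0933 CPM ± 0.0869 (1 to 7 counts per library, n = 8) to 1.51 ± 0.525 (21 to 82 counts, n = 8), and Onecut1, from 0.0354 ± 0.0471 (0 to 4 counts) to 0.377 ± 0.217 (3 to 21 counts). Both were also near 0 in Tcerg1+/- striatum, so only the Q140 groups could bring them past the filter on low counts. Members silent in every group were not tested, so the share that rose is not a result about the list.

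Camera, a test of a list against all other genes over 240 list tests, gave adjusted p values with the preset correlation of 1.29e-93 for projection neuron, 7.36e-21 for indirect pathway, 2.02e-08 for clustered protocadherin, 6.30e-10 for glutamate receptor, 0.00914 for direct pathway, 0.0327 for cortical excitatory and 0.0415 for heat shock genes. With an estimated correlation between genes these were adjusted p = 6.11e-05, 2.22e-04, 0.0225, 0.0558, 0.213, 0.481 and 0.815. The projection neuron, indirect pathway and protocadherin calls of this comparison and of Q140 Tcerg1+/- against Tcerg1+/- in striatum were the 6 of all 59 camera calls that held with an estimated correlation.

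**Figure D2:**
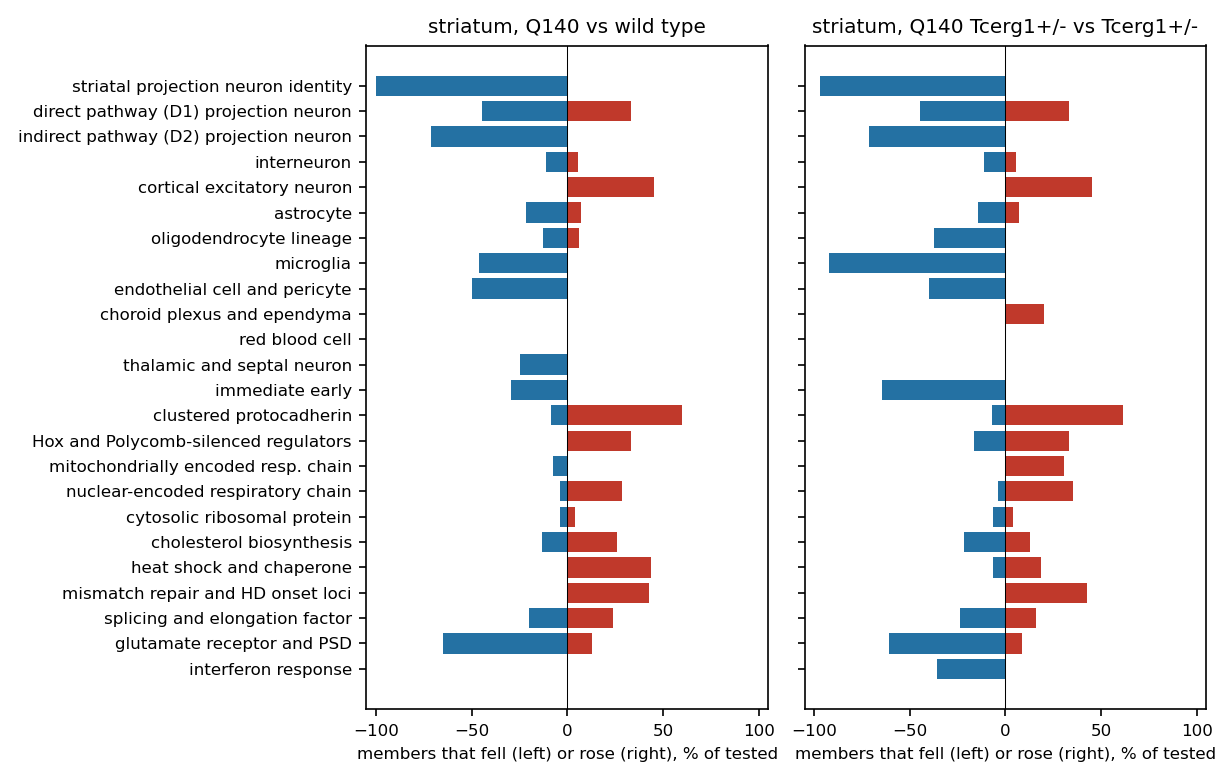
Percent of the tested members of each list (y axis) that fell (bars to the left) or rose (bars to the right) at an edgeR adjusted p below 0.05 over all genes in striatum, for Q140 against wild type and for Q140 Tcerg1+/- against Tcerg1+/- (n = 8 per group). In the left comparison all 30 projection neuron genes fell and 34 of 57 clustered protocadherins rose, and neither list changed the sign of its median under another scaling.

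The other lists showed smaller or mixed changes in Q140 striatum, and none of them passed camera. Fry, which tests a list without regard to the other genes, passed 11 of the 24 lists in this comparison, where camera passed 7. Of 13 microglial genes 6 fell and 0 rose (7 adjusted over the list alone), with Cd68 at -0.18 and Csf1r at -0.12, and of 10 endothelial and pericyte genes 5 fell and 0 rose (the same over the list alone), with Abcc9 at -0.26 and Rgs5 at -0.25. Immediate early genes, which follow neuronal activity, had 5 that fell and 0 that rose of 17 (4 over the list alone), with Egr2 (-1.02), Homer1 (-0.63) and Egr3 (-0.40). Mismatch repair and other genes at loci that modify the onset of Huntington disease had 6 that rose and 0 that fell of 14 (the same over the list alone), with Exo1 (0.62), Rrm2b (0.23), Msh2 (0.17) and Msh3 (0.14). Nuclear-encoded respiratory chain genes had 22 that rose and 3 that fell of 77 (the same over the list alone), with Atp5g1 (0.26) upward and Ndufs3 (-0.20) downward. The splicing and elongation factors, the group to which the TCERG1 protein belongs by function, had 6 that rose and 5 that fell of 25 (7 and 5 over the list alone), with Polr2a (0.53) and Cdk9 (-0.21). Cholesterol biosynthesis had 6 that rose and 3 that fell of 23 (the same over the list alone), with Mvk (0.20) and Insig1 (-0.30).

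Members that passed were few in the remaining lists. Interneuron genes had 1 that rose and 2 that fell of 18 (the same adjusted over the list alone), Cck (0.56), Nos1 (-0.18) and Slc5a7 (-0.12). The astrocyte list had 1 that rose and 3 that fell of 14, the oligodendrocyte lineage list 1 and 2 of 16, and the thalamic and septal list 0 and 2 of 8 (each the same over the list alone), with S100b (0.16), Slc1a2 (-0.18), Olig1 (0.14), Plp1 (-0.22) and Prkcd (-0.24). Cytosolic ribosomal genes had 3 that rose and 3 that fell of 80 (0 and 1 over the list alone), with Rpl3 (0.13) and Rpl31 (-0.25), and the mitochondrially encoded genes had mt-Nd1 (-0.10) downward of 13 (0 over the list alone). The medians of the astrocyte, oligodendrocyte, mitochondrially encoded and ribosomal lists changed sign on FPKM. The ribosomal median of 0.00 lay above 0 and its mean of -0.00 below, and camera pointed up (adjusted p = 0.913). No gene passed by edgeR among 10 choroid plexus and ependyma genes, 4 red blood cell genes and 14 interferon response genes.

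The same Q140 change was then measured on the other background, by comparing Q140 Tcerg1+/- with Tcerg1+/- striatum. Projection neuron genes fell again, 29 of 30 (30 adjusted over the list alone), with Pde10a at -0.84, Arpp21 at -0.81 and Rgs9 at -0.70, and 5 of 7 indirect pathway genes fell (adjusted p with an estimated correlation 3.19e-04), with Penk at -1.21. Protocadherins had 35 that rose and 4 that fell (36 and 5 over the list alone), and glutamate receptor genes 2 and 14. Sfmbt2 (2.03, SE 0.104), Dsp (1.57), Fam196b (1.38), Ipcef1 (1.30), Rprm (1.29), Tnnt2 (1.17) and Pcdh20 (1.17) were among the largest rises, and Gpx6 (-2.56, SE 0.138, edgeR adjusted p = 7.98e-16), Ddit4l (-1.98), Cpne9 (-1.96), Gm9754 (-1.87), Slc4a11 (-1.77), Odf4 (-1.76) and Egr2 (-1.73) among the largest falls. Immediate early genes had 11 that fell and 0 that rose of 17 (adjusted p = 0.00321, and adjusted p = 0.771 with an estimated correlation) and microglial genes 12 that fell of 13 (adjusted p = 0.0136, and adjusted p = 0.759 with an estimated correlation), with Csf1r at -0.16 and C1qa at -0.26. Camera also passed 5 lists here, each at an adjusted p that an estimated correlation ended. They were nuclear-encoded respiratory chain (27 rose and 3 fell of 77, adjusted p = 0.00542, 0.815 estimated), direct pathway (3 and 4 of 9, 0.00914, 0.213 estimated), Polycomb-silenced regulators (2 and 1 of 6, 0.0228, 0.144 estimated), mismatch repair (6 and 0 of 14, 0.0429, 0.585 estimated) and cortical excitatory genes (5 and 0 of 11, 0.0498, 0.533 estimated). The call for Polycomb-silenced regulators carries the limit given above, since Wt1 and Onecut1 passed the filter through the Q140 groups.

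In this comparison 6327 genes passed by edgeR, 3228 upward and 3099 downward, with 7787 on FPKM by limma-trend, 5750 upward and 2037 downward. Of the genes called on each background, 2287 rose on both (535 expected if independent) and 2272 fell on both (481 expected), and 0 went in opposite directions. Across all tested genes, which are not independent replicates, the log2 fold changes on the backgrounds had a Pearson correlation of 0.816 and a Spearman correlation of 0.745, with a total least squares slope of 1.05. In cortex the same correlations were 0.194 and 0.173.

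**Figure D3:**
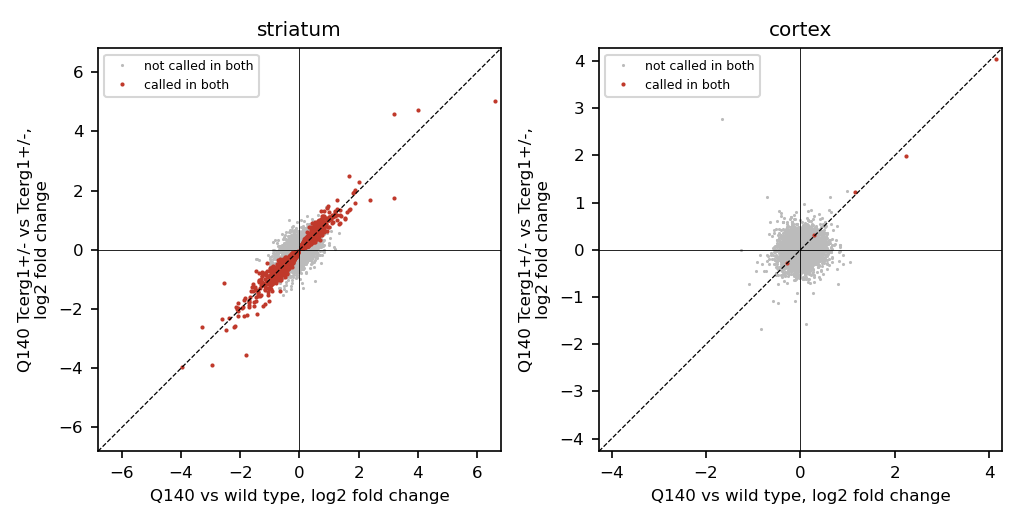
Log2 fold change of each tested gene for Q140 against wild type (x axis) and for Q140 Tcerg1+/- against Tcerg1+/- (y axis) in striatum and cortex; points are genes, red where both comparisons called them and grey otherwise, and the dashed line marks equal change. The Pearson correlation across genes is 0.816 in striatum and 0.194 in cortex.

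In cortex, Q140 against wild type asked whether the change reached beyond the striatum. Few genes changed. Among those of at least 1 log2 CPM, Il33, which encodes an alarmin cytokine that oligodendrocytes and astrocytes make, fell from 37.2 CPM ± 2.40 (SD, n = 8) to 29.4 ± 2.69 (n = 8), a log2 fold change of -0.33 (SE 0.0509, edgeR adjusted p = 4.35e-04). The glial genes Tspan2 (-0.30), Car2 (-0.21) and Glul (-0.12) and Atraid (-0.28) fell too, and Abhd1 (1.16, SE 0.0929, adjusted p = 5.96e-11) and the mitochondrial ribosome gene Mrpl33 (0.28, adjusted p = 0.00565) rose. Weaker calls were Entpd2 (-0.32, kept in 23 of the 32 fits that left out 1 library), Slc12a7 (0.53, kept in 24), Pdpn (0.37, kept in 24), Abca8a (0.36, kept in 21) and Cgref1 (0.30, kept in 10). No member of any list passed over all genes. Oligodendrocyte lineage genes were lower as a list, with 9 of 16 falling adjusted over the list alone and a median of -0.15, and with Mobp (-0.29) and Plp1 (-0.28), and camera gave an adjusted p = 6.30e-10 (adjusted p = 0.21 with an estimated correlation). The median of the projection neuron list was -0.02 and camera did not call it (adjusted p = 0.222).

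In total 14 genes passed in cortex, 8 upward and 6 downward (16 and 22 with the DESeq2 Wald test), with 1527 at an unadjusted p below 0.05. The count was 9 without the Q140 F4 library, without Q140 M4 or without wild type F3, and 27 without Tcerg1+/- F2. Camera also passed 6 other lists, nuclear-encoded respiratory chain (downward, adjusted p = 2.60e-06, 0.725 with an estimated correlation), cholesterol biosynthesis (downward, 8.40e-06, 0.481 estimated), interferon response (upward, 3.53e-04, 0.431 estimated), cortical excitatory (downward, 0.00914, 0.0837 estimated), interneuron (downward, 0.0157, 0.21 estimated) and mitochondrially encoded genes (downward, 0.0269, 0.771 estimated). Of the genes tested in both tissues, 5 that rose in cortex also rose in striatum (1.37 expected if independent) and 5 that fell also fell (0.932 expected). Of the 14 cortical calls, 5 that rose and 1 that fell start within 10 Mb of Htt. The overlap was not counted without those genes, so it does not measure a shared response away from Htt.

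Q140 Tcerg1+/- against Tcerg1+/- in cortex called 9 genes, 6 upward and 3 downward (1253 unadjusted, 25 without Tcerg1+/- F2). The balance turned under some settings, with 9 upward and 24 downward by the DESeq2 Wald test and 6 and 7 without the mice Q140 F1 and Tcerg1+/- M3. Abhd1 (1.22, SE 0.0931, edgeR adjusted p = 1.49e-11) and Mrpl33 (0.32, adjusted p = 8.71e-04) rose again and Atraid (-0.29) fell again, along with Lingo1 (-0.25, adjusted p = 0.00453), which encodes an inhibitor of myelination, and Gpd1 (-0.21, adjusted p = 0.00707), a glycerol phosphate enzyme of oligodendrocytes. No list member passed over all genes, 5 of 23 cholesterol genes fell adjusted over the list alone, and camera passed cholesterol (adjusted p = 3.98e-05, 0.533 with an estimated correlation), glutamate receptor (0.00819, 0.278 estimated) and oligodendrocyte genes (0.0187, 0.771 estimated), all downward. The average of both Q140 comparisons, which uses all 32 cortical libraries, called 118 genes, 47 upward and 71 downward (64 and 37 on FPKM). Besides Abhd1 and Mrpl33 it raised Abca8a (0.32), Gng11 (0.30) and Cgref1 (0.26), and it lowered Gm37885 (-0.29) and the sterol regulator Insig1 (-0.28). Abhd1, Mrpl33, Cgref1 and Insig1 start within 10 Mb of Htt. The somatostatin receptor Sstr2 (-0.29) was kept in 8 of the 32 fits that left out 1 library. The count was 70 without wild type F2, 73 without wild type M3, 74 without Q140 Tcerg1+/- M3 and 303 without Tcerg1+/- F2. Of the genes called on average in both tissues, 22 rose in both (11.6 expected if independent), 46 fell in both (15.6 expected) and 14 went in opposite directions.

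Genes near Htt were called more often than others in the cortical Q140 comparisons. Of the 191 tested genes that start within 10 Mb of Htt, 6 were called in Q140 against wild type, 5 that rose and 1 that fell, against 8 of 17508 other genes (Fisher's exact test, two-sided, odds ratio 70.7, p = 4.08e-09, adjusted p = 4.9e-08). On the Tcerg1+/- background 6 neighbours and 3 other genes were called (odds ratio 188, Fisher's exact p = 1.19e-10, adjusted p = 2.86e-09). For the average Q140 effect 11 neighbours and 107 other genes were called (odds ratio 9.94, Fisher's exact p = 6.08e-08, adjusted p = 4.86e-07), so most of those calls lay elsewhere. Abhd1 (ENSMUSG00000006638, chromosome 5, 30950066 to 30955091) had a mean of 5.92 CPM in the 16 cortical libraries labelled Q140 and of 2.59 in the other 16. Atraid (ENSMUSG00000013622, 31048312 to 31054623) had 30.2 and 36.7, Mrpl33 14.6 and 11.8, and Cgref1 11.3 and 9.44. The pseudogenes Gm6089 (1.08 and 0.247), Gm5067 (1.04 and 0.48) and Gm2420 (0.505 and 0.0257) were low, and their reads cannot be assigned with certainty. In striatum 78 of 194 neighbours of Htt (40.2%) and 32.1% of the other genes were called, which did not pass (adjusted p = 0.0689), while 79 of 181 neighbours of Tcerg1 (43.6%) against 32% did (Fisher's exact, adjusted p = 0.00786). The latter is the protocadherin result again, since all 57 clustered protocadherins tested lie among these neighbours, and without them 40 of 124 (32.3%) were called (odds ratio 1.01, Fisher's exact p = 1, a test added after the values were seen). No neighbour of Tcerg1 was called by edgeR under the Tcerg1+/- label, of 181 in striatum and 178 in cortex.

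**Figure D4:**
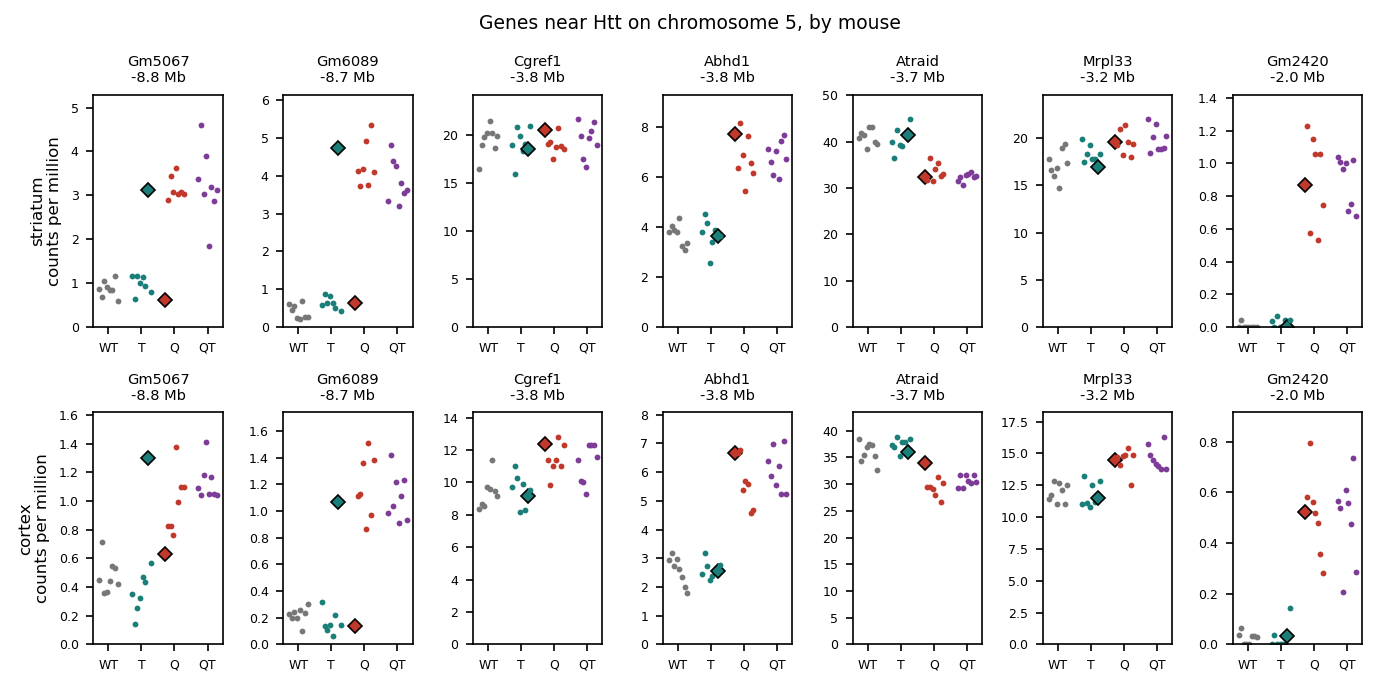
CPM (y axes, from 0) of 7 genes within 10 Mb of Htt on chromosome 5 in striatum and cortex, by genotype (WT wild type, T Tcerg1+/-, Q Q140, QT Q140 Tcerg1+/-, n = 8 each); points are mice in replicate order, diamonds mark Q140 F1 and Tcerg1+/- M3, and titles give the distance to Htt. At Gm6089 and Gm5067 both marked mice lie with the other Q140 label in both tissues, and at Abhd1 they lie with their own.

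Whether the Q140 change differed between the tissues was tested directly, striatum minus cortex, with the mouse as a block. It did for 3987 of 18742 genes by edgeR, 1796 upward and 2191 downward, and 5272 on FPKM by limma-trend, 3804 upward and 1468 downward. Sfmbt2 (1.85, SE 0.157, adjusted p = 1.99e-12) and Rprm (1.42) rose more in striatum, and Cpne9 (-2.08, SE 0.165, adjusted p = 7.64e-11), Ddit4l (-1.81) and Mas1 (-1.68) fell more. Cpne9 was 17.5 CPM ± 2.46 (SD, n = 8) in wild-type striatum and 4.09 ± 0.883 (n = 8) in Q140 striatum, and in cortex 124.7 ± 11.4 and 123.0 ± 16.1 (n = 8 each). Other large differences rested on a tissue in which the gene was near 0. Those were Satb2 (1.76, not passed on FPKM with a pseudocount of 1), Neurod2 (1.60), Sec14l3 (-2.08), Ptpn7 (-2.28, 0.0204 CPM in wild-type cortex) and Nkx2-1 (2.11, adjusted p = 0.0335). Nkx2-1 did not pass with DESeq2 or on FPKM, and in striatum its level was 6.35 CPM in wild type and 6.04 in Q140. For the Tcerg1+/- label 0 genes passed for a difference between the tissues by edgeR, with 651 genes at an unadjusted p below 0.05 on the wild-type background and 767 on the Q140 background. DESeq2 and limma-trend on FPKM also called 0 in both, and edgeR with no filter on low counts called 21 in each.

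What the Tcerg1+/- label changed on its own was asked against wild type. Very few genes moved besides Tcerg1. In striatum Guf1 (ENSMUSG00000029208, chromosome 5, 69556923 to 69575973), which encodes a mitochondrial translation factor, rose from 58.5 CPM ± 3.42 (SD, n = 8) to 69.6 ± 2.99 (n = 8), a log2 fold change of 0.25 (SE 0.042, edgeR adjusted p = 0.00413). Gabpb2 (ENSMUSG00000038766, chromosome 3, 95181766 to 95217916), a subunit of the GA-binding transcription factor, fell from 55.5 ± 1.43 to 48.2 ± 2.20 CPM (n = 8 each; -0.20, SE 0.0273, adjusted p = 5.61e-05). In cortex Guf1 rose by the same amount (0.25, SE 0.0415, adjusted p = 0.00348), and Cpeb1 (ENSMUSG00000025586, chromosome 7, 81347026 to 81455465), which controls translation of polyadenylated mRNA, rose by 0.24 (SE 0.0334, adjusted p = 9.65e-05). Weaker cortical calls were the mitofusin gene Mfn1 (0.16, kept in 26 of the 32 fits that left out 1 library), Trip12 (0.12, kept in 12) and Adam15 (-0.13, kept in 4). In all 3 genes passed in striatum and 6 in cortex (6 and 12 with the DESeq2 Wald test), with 1029 and 1109 at an unadjusted p below 0.05. The cortical count was 3 without Tcerg1+/- M1 and without each of wild type F1, F2, F4, M1 and M3. No list member passed over all genes. Camera passed immediate early (upward, adjusted p = 0.0125, 0.815 with an estimated correlation), heat shock (upward, 0.00289, 0.759 estimated) and ribosomal genes (downward, 0.0498, 0.815 estimated) in striatum and immediate early genes in cortex (upward, 0.0372, 0.815 estimated). The ribosomal call passed under 1 of 5 alternatives.

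The same label was then compared within Q140 mice, which is where a modifier of the disease would act. In striatum the 24 called genes, 14 upward and 10 downward (9 and 13 on FPKM, 41 and 25 with the DESeq2 Wald test), included Guf1 (0.28, SE 0.0411, edgeR adjusted p = 3.23e-04) and Gabpb2 (-0.19, adjusted p = 3.23e-04) again. Upward were 1810022K09Rik (0.44, SE 0.0735, adjusted p = 0.00194), the chromatin gene Atad2b (0.27), the DNA demethylase Tet2 (0.21, not passed on FPKM) and the kinase Chuk (0.20, kept in 21 of the 32 fits that left out 1 library). Downward were the carnosine synthase Carns1 (-0.28, adjusted p = 0.0062), the deacetylase Sirt7 (-0.21, adjusted p = 0.00106), Fam98a (-0.20) and Reep4 (-0.42, adjusted p = 0.0191, and adjusted p = 0.0504 without Q140 Tcerg1+/- F2). In cortex 7 genes passed, 6 upward and 1 downward. Besides Tcerg1 they were 1810022K09Rik (0.39), Guf1 (0.30), Tbc1d31 (0.27), Il33 (0.26), Cpeb1 (0.19) and Adam15 (-0.16, adjusted p = 0.0026). Tbc1d31 did not pass without Q140 F3 (adjusted p = 0.0557), Q140 M1 (0.0583), Q140 Tcerg1+/- F4 (0.0576) or Q140 Tcerg1+/- M3 (0.053). Il33 (SE 0.0512, adjusted p = 0.026, kept in 21 of the 32 fits) went from 29.4 CPM ± 2.69 (SD, n = 8) in Q140 to 35.4 ± 2.07 (n = 8) in Q140 Tcerg1+/- and was 37.2 ± 2.40 (n = 8) in wild type. In Tcerg1+/- cortex it was 37.2 ± 3.28 (n = 8). A return toward wild type would be tested by the interaction below, which no gene passed. Between the tissues, 3 of these genes rose in both and 1 fell in both.

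No list member passed over all genes for the Tcerg1+/- label in Q140 mice, in either tissue. Mitochondrially encoded respiratory chain genes were higher in striatum, with 8 of 13 rising adjusted over the list alone and camera adjusted p = 6.66e-10, and in cortex at adjusted p = 3.69e-04, with adjusted p = 0.114 and 0.615 with an estimated correlation. Between the same striatal groups the share of mitochondrial reads went from 6.12% (SD 0.183, n = 8) to 6.39% (SD 0.172, n = 8) and that of the 10 highest genes from 6.96% to 7.24%, and whether this reflects the tissue or the libraries was not tested. Nuclear-encoded respiratory chain genes were higher too, at 0.00819 and 9.68e-08 (0.815 and 0.655 estimated), and in striatum glutamate receptor genes at 0.0122 (0.725 estimated). Lower in striatum were microglial genes at 0.0036 (0.725 estimated) and, at adjusted p values between 0.0245 and 0.0474, oligodendrocyte, cholesterol, interferon, choroid plexus, immediate early and heat shock genes, none of which passed with an estimated correlation. Lower in cortex were interferon genes at 0.00365 (0.592 estimated) and, at 0.0498, microglial (0.779 estimated) and heat shock genes (0.815 estimated). The heat shock call in cortex passed under 0 of 5 alternatives and the microglial under 2. The striatal comparison had 1387 genes at an unadjusted p below 0.05 and the cortical 913.

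Whether the Tcerg1+/- label altered the Q140 effect was tested as an interaction. By edgeR 0 of 17901 genes passed in striatum and 0 of 17752 in cortex, with 629 and 664 at an unadjusted p below 0.05, and DESeq2 and limma-trend on FPKM also called 0. In simulated data with the same sizes, 70% of striatal and 64% of cortical genes with an added interaction of 1.5-fold were recovered, and 78% and 88% of those with 2-fold. Smaller interactions were mostly missed, with 40% and 34% recovered at the next smaller fold simulated and 2% and 6% at 1.1-fold. Camera passed 7 lists in striatum and 5 in cortex and none with an estimated correlation. The lowest were immediate early (downward, adjusted p = 3.98e-05, 0.725 estimated), mitochondrially encoded (upward, 2.76e-06, 0.278 estimated) and heat shock genes (downward, 7.77e-06, 0.533 estimated) in striatum and nuclear-encoded respiratory chain genes (upward, 4.79e-05, 0.759 estimated) in cortex.

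A single score per mouse summed up the Q140 change, as the mean log2 level of the genes called for the average Q140 effect, signed by their direction. The genes were picked and signed on these same libraries, so the gap between mice with and without Q140 is set in part by the pick. Its size is not to be compared between the tissues, and only the difference between backgrounds is tested. In striatum (8380 genes, 4393 upward and 3987 downward, and 7435 and 2519 on FPKM) the score relative to wild type was -0.005 ± 0.015 (SD, n = 8) in Tcerg1+/-, 0.241 ± 0.007 (n = 8) in Q140 and 0.248 ± 0.016 (n = 8) in Q140 Tcerg1+/-. The Q140 effect was 0.24 on the wild-type background and 0.25 on the Tcerg1+/- background, a difference of 5% of the average effect (95% bootstrap interval -3.06% to 13%, two-sided permutation p = 0.252). With 1 library left out the difference ran from 2.54% (without wild type M1, and 2.64% without wild type F3) to 7.52% (without Q140 Tcerg1+/- F4). In cortex (118 genes) the effects were 0.20 and 0.23, a difference of 9.97% (-8.22% to 27%, permutation p = 0.323), and -7.85% (without wild type M4) to 16.9% (without Tcerg1+/- M4) with 1 library left out. For the projection neuron list alone the striatal effects were -0.56 and -0.55, a difference of -1.72% (-14% to 10.5%, permutation p = 0.798), and in cortex, where the effect was near 0, 11.3% (-148% to 296%, permutation p = 0.895). An attenuation by 22.2% added to simulated data was estimated at -23.2% in striatum (permutation p = 2e-05, the smallest the draws can give is 1e-05) and -20.4% in cortex (permutation p = 0.00027). Those simulated scores held 149 and 150 genes drawn independently of each other, so their p values do not give the power for the real scores.

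**Figure D5:**
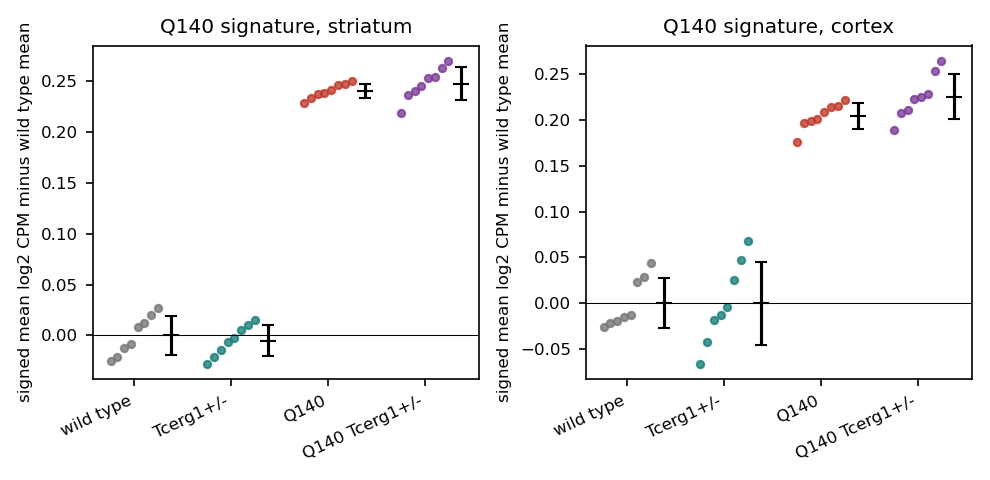
Q140 score of each mouse (y axis, signed mean log2 CPM minus the wild-type mean) in striatum and cortex by genotype (x axis, n = 8 per group); points are mice ordered by level within the group and bars are means with 1 SD. Striatal Q140 mice lie between 0.229 and 0.25 and Q140 Tcerg1+/- mice between 0.219 and 0.27.

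No gene passed for a difference of the Q140 effect between females and males in either tissue. By edgeR 0 genes passed, with 859 at an unadjusted p below 0.05 in striatum and 586 in cortex, and DESeq2 and limma-trend on FPKM also called 0. For Tcerg1 the difference, female minus male, was 0.04 (SE 0.0367, adjusted p = 0.963) in striatum and -0.06 (SE 0.0384, unadjusted p = 0.135) in cortex. In simulated data 80% of striatal and 82% of cortical genes with an added sex difference of 1.5-fold were recovered, and 4% and 2% of those with 1.1-fold.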

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

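The tests of explanations for the 3 patterns weighed here were chosen after the results were seen, apart from the correction for gene length and GC content and the random splits.

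Genes whose Q140 response differed between the tissues were the largest group. There were 3987, found by testing the difference itself, and 1 of 24 splits of the mice, the real one, called as many (highest other 1). The share cannot fall below 1 of 24 here, so chance is argued against but not excluded by the splits alone. The log2 Q140 effect in striatum minus that in cortex was positive for Tcerg1 (0.25), Nkx2-1 (2.11), Sfmbt2 (1.85), Satb2 (1.76), Neurod2 (1.60) and Rprm (1.42) and negative for Ptpn7 (-2.28), Sec14l3 (-2.08), Cpne9 (-2.08), Ddit4l (-1.81) and Mas1 (-1.68). These are differences of change and not of level, as Satb2 was 0.849 CPM in Q140 striatum and 118.2 in Q140 cortex. Nkx2-1 (6.35 CPM in wild-type and 6.04 in Q140 striatum) did not pass with DESeq2 or on FPKM, and Satb2 not on FPKM with a pseudocount of 1.

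Single mice lay far from the other 7 of their group at genes that mark neurons or sit near Htt. Of 104 groups looked at, 13 held such a mouse, and 5.2 would by chance if the groups were independent. They are not, since Q140 F1 and Tcerg1+/- M3 were counted again over linked pseudogenes and over tissues, so the excess is not a test. The projection neuron gene Ppp1r1b was 1830 CPM in the striatum of Q140 M2 (others 1520 to 1588), 1360 in Q140 Tcerg1+/- F3 (others 1554 to 1644), and 95.6 in the cortex of Tcerg1+/- M1. The cortical marker Slc17a7 was 12.5 in the striatum of Q140 M4 and 4.52 in wild type F3. On chromosome 5, the pseudogene Gm6089 was 0.62 in the striatum and 0.14 in the cortex of Q140 F1, and 4.74 and 1.07 in Tcerg1+/- M3. The neighbouring pseudogene Gm5067 was 0.62 in the striatum of Q140 F1, 3.13 and 1.30 in the striatum and cortex of Tcerg1+/- M3, and 1.41 in the cortex of Q140 Tcerg1+/- F4.

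Called cortical Q140 genes clustered near Htt. A candidate explanation is a segment of another strain carried along with the Q140 allele, since gene targeting often leaves such DNA. That the neighbours held 6 of 14 calls (Fisher's exact p = 4.08e-09) is the pattern itself and would follow from an effect of the mutant allele on nearby genes too, so it supports neither. At Gm6089 and Gm5067, 2 mice had levels against their Q140 label in both tissues, Q140 F1 and Tcerg1+/- M3, which argues against an effect of the mutant allele on these pseudogenes. The same mice had Abhd1 levels of their own label, and 0 of 32 mice went against the label there, which argues against wrong Q140 labels. Of the other called neighbours, 3 of 5 had no mouse that went against the label in both tissues, so a strain variant and an effect of the mutant allele on them cannot be told apart without a recombinant mouse at those genes. Without both mice the cortical Q140 count was 15.

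Tcerg1 reads were higher in mice labelled Tcerg1+/-, where loss of 1 copy would lower them. A gain of a chromosome segment that spans its neighbours is argued against, since the highest median log2 change of the 9 genes within 1 Mb over the 4 comparisons was 0.00758 (SD 0.066) and 0 of them were called. The highest single value was 0.478, in cortex for Q140 Tcerg1+/- against Q140 (SD 0.186). A gain limited to Tcerg1, or to Tcerg1 and 1 neighbour, cannot be judged from this median. Scaling is argued against too, since the lowest log2 change over 16 values under other scalings was 0.453 (highest adjusted p 2.23e-14). Exchanged Tcerg1 labels stay open. The lowest ratio of the unlabelled to the labelled group was 0.668 (SE 0.0123) and the others were 0.671, 0.704 and 0.716. A lost copy without any reads, and without a rise of the other copy, predicts a lower ratio than all of these. An exchange in which part of the reads is kept or made up for remains possible. A ratio of 1 or more was set to speak against an exchange. It could not arise, since higher reads under the label are the pattern itself. Whether another gene or label could decide the question was not tested. A mutant allele that makes a stable or raised transcript could give the same values and was not tested.

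Projection neuron genes were lower in Q140 striatum. Cortical tissue in the samples is argued against, since a median fall of this size needs a share of 36.9%, and the 6 genes with at least 100 CPM in cortex and at least 10 times the striatal level allow at most 1.18% (Cux2), with Slc17a7 at 4.69 CPM where that share would give 490. This test was narrowed to those 6 genes after a version with all 11 cortical excitatory genes had decided nothing, because Rprm allowed 57.7% and Lamp5 5.75%. A lower share of neurons as the whole cause is argued against, since it would raise glial and vascular markers alike, and of 53 such genes 16 fell and 2 rose. This depends in part on the scaling, since on FPKM 5 fell and 3 rose, with list medians above 0 for astrocytes (0.0209) and oligodendrocytes (0.0375) and below 0 for microglia (-0.0407) and endothelium (-0.0741). Gene length and GC content explained 0.786% of the variance, and the list's median was -0.485 after their removal and -0.482 before. Lower expression within the neurons remains a hypothesis that may hold for these genes, alone or along with a smaller loss of cells.

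Random splits of the mice within each tissue asked whether chance could give as many calls. Chance is argued against in striatum for Q140 against wild type (5746 genes, 1 of 100 splits as large, highest other 3264), Q140 Tcerg1+/- against Tcerg1+/- (6327, 1, highest other 3939), the average Q140 effect (8380, 1, highest other 2) and Q140 Tcerg1+/- against Q140 (24, 1, highest other 7). In cortex it is argued against for Q140 against wild type (14, 1, highest other 2), Q140 Tcerg1+/- against Tcerg1+/- (9, 1, highest other 6), the average Q140 effect (118, 1, highest other 46) and Tcerg1+/- against wild type (6, 1, highest other 2). Of these calls, 6 of 14 for Q140 against wild type and 6 of 9 on the Tcerg1+/- background start within 10 Mb of Htt. Elsewhere 8 and 3 genes were called, and the splits were not counted without the genes near Htt. With 3 genes against a highest other count of 6, the splits do not exclude chance for calls away from Htt on the Tcerg1+/- background. Chance is not excluded for Tcerg1+/- against wild type in striatum (3 genes, 3 of 100 splits as large, highest other 34). Nor is it for Q140 Tcerg1+/- against Q140 in cortex (7 genes, 2 of 100, highest other 191), since other splits called more. For the counts of 0 by edgeR no split can call fewer, so the comparison says nothing about chance. All were as large, 100 of 100 for the interaction in striatum (highest other 1, 629 genes unadjusted) and cortex (1, 664 unadjusted) and for the sex difference in striatum (80, 859 unadjusted) and cortex (1, 586 unadjusted), and 24 of 24 for the tissue difference of the Tcerg1+/- label on the wild-type (2, 651 unadjusted) and Q140 background (0, 767 unadjusted). DESeq2 and limma-trend on FPKM gave 0 for each of these too. Splits with 34 genes against 3 and 191 against 7 called several times the real count and, like that with 80 genes where the real count was 0, point to a structure of the samples, the source of which was not tested. The animal label begins with a number that mice of several genotypes share, and it was neither fitted nor held together in the splits.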

How the results depend on the processing

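The alternatives for the average effect of the Tcerg1+/- label and the fit without the mice Q140 F1 and Tcerg1+/- M3 were chosen after seeing the data, as were those for the cortical excitatory genes and the glial and vascular markers. The large striatal counts stayed within 1.5 times, but the share that rose for Q140 against wild type went from 51.7% to 76.2% on FPKM. Q140 against wild type called 5398 to 5793 striatal genes with 1 library left out, and Q140 Tcerg1+/- against Tcerg1+/- 5902 to 6339. Over all named genes no direction reversed. Of 155 gene values, 154 kept their side of the threshold with DESeq2 size factors, 154 with the DESeq2 Wald test, 154 with a mean count of at least 50, 145 with no filter and 140 with each FPKM pseudocount. Of 142, 129 did so without the sex term, 128 with plate column and 131 with the replicate block. With 1 library left out 4230 of 4544 did, and all others lost the call in the same direction.

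Cortical counts and small striatal counts moved most, and the cause was not tested unless one is given. The DESeq2 Wald test called more genes for Q140 against wild type in cortex (38), Q140 Tcerg1+/- against Tcerg1+/- in cortex (33), Q140 Tcerg1+/- against Q140 in striatum (66) and cortex (11), Tcerg1+/- against wild type in striatum (6) and cortex (12), the average Q140 effect in cortex (242) and the average Tcerg1 effect in striatum (136) and cortex (76). The replicate block gave 78 genes for the average Q140 effect in cortex. A mean count of at least 50, which tests fewer genes, gave 5 for Q140 Tcerg1+/- against Tcerg1+/- in cortex. Fitting only the libraries compared, with fewer samples, gave 3 for Tcerg1+/- against wild type in cortex. With no filter, 21 genes differed between tissues for the Tcerg1+/- label on the wild-type background and 21 on the Q140 background.

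With 1 library left out, cortical counts ranged from 70 (without wild type F2) to 303 (without Tcerg1+/- F2) for the average Q140 effect, 9 to 27 for Q140 against wild type (9 without Q140 F4, Q140 M4 or wild type F3, 27 without Tcerg1+/- F2), 8 to 25 for Q140 Tcerg1+/- against Tcerg1+/- (25 without Tcerg1+/- F2) and 3 to 7 for Tcerg1+/- against wild type (3 without Tcerg1+/- M1 or wild type F1, F2, F4, M1 or M3). The average Q140 count was also 73 without wild type M3 and 74 without Q140 Tcerg1+/- M3. Without Q140 F1 and Tcerg1+/- M3 all 14 counts stayed within 1.5 times. For Q140 against wild type in striatum, 5 to 6 cortical excitatory genes were called with 1 compared library left out, and 8 glial and vascular markers on FPKM (3 rose and 5 fell).

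Gene list calls depended on the correlation assumed between genes. With an estimated correlation 3 lists passed for Q140 against wild type and 3 for Q140 Tcerg1+/- against Tcerg1+/- in striatum, and 0 in each of the other striatal and cortical contrasts, since the estimate widens the null spread. For Q140 Tcerg1+/- against Q140 in cortex 3 lists passed with DESeq2 size factors and 3 without the sex term. For Tcerg1+/- against wild type 0 passed in cortex without the sex term and 6 in striatum with plate column. Fry passed 11 lists for Q140 against wild type, 12 for Q140 Tcerg1+/- against Tcerg1+/- and 2 for Q140 Tcerg1+/- against Q140 in striatum. It passed 1 for Q140 against wild type in cortex and 0 in each of the other contrasts.

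The Q140 score's difference between backgrounds passed under no setting but changed sign under some. In striatum it was -1.72% with the projection neuron list and -7.94% (permutation p = 0.0514) with genes picked from Q140 against wild type. In cortex it was -16.1% (permutation p = 0.0609) with such genes, -0.948% with genes picked by DESeq2, and -7.85% (without wild type M4) to 16.9% with 1 library left out. Picking genes on the wild-type background favours a smaller effect on the other by construction. The across-gene correlation of the Q140 effect on the backgrounds in striatum was 0.886 on FPKM with a pseudocount of 1, 0.91 with a mean count of at least 50 and 0.18 with no filter, and 0.00916 in cortex with no filter, where the genes added have few counts and the cause was not tested further. Small effects were mostly missed at this design, since 18% of 1.1-fold changes added to simulated striatal data were recovered.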

Other observations

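The average effect of the Tcerg1+/- label over both backgrounds, and its other splits and alternatives, were added after the 4 single comparisons had been seen.

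A small set of genes went with the label, upward and downward, and some were called in both tissues. Averaged over backgrounds, 71 genes passed in striatum, 42 upward and 29 downward (84 on FPKM, 30 and 54), and 25 in cortex, 19 upward and 6 downward, with 1702 and 1275 at an unadjusted p below 0.05. The DESeq2 Wald test called 136 in striatum and 76 in cortex. The 13 genes called in both tissues all changed in the same direction (0.104 expected if independent). These counts and those below include Tcerg1 itself, and without it 70 genes passed in striatum, 24 in cortex and 12 in both. The mitochondrial translation factor Guf1 rose by 0.27 (SE 0.0294) on the log2 scale in striatum and 0.28 (SE 0.0293) in cortex, and Mfn1, which fuses mitochondria, by 0.11 and 0.14. The translation regulator Cpeb1 rose by 0.21 and 0.22, and the nucleolar RNA-binding gene Rbm28 by 0.27 and 0.17. The ubiquitin genes Trip12 (0.10 and 0.10) and Usp48 (0.13 and 0.10), the kinase Chuk (0.19 and 0.12) and 1810022K09Rik (0.30 and 0.32) rose, and the metalloprotease Adam15 (-0.12 and -0.15) fell. Gabpb2 fell in striatum (-0.19, adjusted p = 2.63e-08) and did not pass in cortex (-0.12, adjusted p = 0.111).

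Of the 71 striatal genes 70 had the same sign in cortex, and of the 25 cortical genes 25 had the same sign in striatum, while across all 17056 genes tested in both the correlation was 0.237 (genes are not independent replicates). Both tissues came from the same mice, so the tissues are not independent samples. Splits that moved mice singly argue against chance for the striatal count (71, 1 of 100 splits as large, highest other 3), the cortical count (25, 1, highest other 1) and the shared genes (13, 1, highest other 0). They did not hold together mice that share the first number of the animal label. A structure of the samples that goes with the Tcerg1+/- label is therefore not excluded. The counts were 52 and 21 without Q140 F1 and Tcerg1+/- M3. Whether these genes follow a lower or a higher dose of Tcerg1 stays open, since the reads go against the label.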
